A study of Homo sapiens with 12 samples.

How the data were processed

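RNA sequencing libraries were made from 2 human metastatic melanoma cell lines, A375 and LOX-IMVI BR, after exposure to a control, to 6-thio-dG at 5 µM or to BIBR1532 at 25 µM, with 2 biological replicates per line and treatment and 12 libraries in all. Per the labels, cells were grown in 6-well plates, total RNA was isolated with TRIzol, and libraries were prepared with a TruSeq kit that does not keep the strand. Reads from overlapping genes on opposite strands therefore cannot be separated, and near-identical gene copies share reads. What BR stands for, the vehicle used for the control and the length of exposure were not given in the sources used here.

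The authors deposited a single table of whole-number counts per gene, not normalized, for the 12 libraries. The submitters' processing notes name STAR, featureCounts 1.5.1, Picard, GATK and the builds hg19 and GRCh37. The role of each tool was not given in the sources used here. The deposited table held 75253 rows, of which 54072 carried NONCODE identifiers of long noncoding genes and 21177 carried gene symbols. A spreadsheet had turned some symbols into dates: 4 rows with 2 ambiguous date names, at most 0.000913% of the counts of a library, were dropped, and 24 further date-like rows were kept but not named. No genomic coordinates were used. GC content came from the longest coding transcript of each gene in GENCODE (the longest transcript where none was coding) and was found for 21007 symbol rows. Counts per library ranged from 11813388 to 25822381. Intervals and limits computed from counts cover counting error only.

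Genes were tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1, DESeq2 1.42.0, with 1.17.8 of the data.table package). Low-count genes were removed with filterByExpr, libraries were scaled by TMM, and 1 mean per line and treatment was fitted to all 12 libraries by robust quasi-likelihood, which left 6 residual degrees of freedom. Of the 29114 genes tested, 14439 carried symbols and 14675 were NONCODE genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. The 9 comparisons were each compound against control in each line, the compounds against each other in each line, the difference between the lines in the effect of each compound, and the control of LOX-IMVI BR against that of A375. Levels are TMM-scaled CPM, counts over the scaled library total, given as mean ± SD of 2 libraries. Log2 fold changes are given ± SE from the fit. The design, the gene lists, the naming rule and the first set of alternatives were chosen before the data were examined.

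Of 32 gene lists fixed in this way, 31 were tested: telomerase and shelterin, p53 targets, DNA repair and damage signalling, DNA replication and E2F targets, mitosis, replication-dependent histones, interferon-stimulated genes, secreted inflammatory factors, apoptosis regulators, ATF4 and unfolded protein response, cholesterol synthesis, fatty acid synthesis, hypoxia and glycolysis, oxidative phosphorylation, NRF2 targets, aryl hydrocarbon receptor targets, heat shock response, metallothioneins, melanocyte differentiation, dedifferentiated melanoma (AXL high), ERK pathway output, extracellular matrix and mesenchymal genes, cytosolic ribosomal proteins, ribosome biogenesis and MYC targets, purine synthesis and thiopurine handling, autophagy and lysosome, and markers of epithelial cells, keratinocytes, fibroblasts, leukocytes and endothelial cells. Mitochondrially encoded transcripts were not analysed here. A list of at least 3 tested members was tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation. Camera compares the members of a list with all other genes. After GC correction these are only the symbol-named genes with a GC value, so a call can also change with the set of genes. Members called over all genes were counted, and again with p adjusted over the list alone. Medians of lists are over the tested members unless said otherwise.

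Genes named from the ranking were the 10 largest rises and the 10 largest falls of each compound against control, and the 5 largest in each direction elsewhere, among called genes with a mean of at least 5 CPM in the higher group and both libraries of that group beyond both of the other. Clone-based and LOC names, pseudogenes, mitochondrial and sex-linked marker genes were left out of the ranking. TERT, CDKN1A, MDM2, AXL, MITF and GDF15 were followed whatever their result, and from each list up to 4 called members with the smallest adjusted p were taken. The text gives a selection of these. A fold against a group without counts is a lower limit, taken against 3 counts over the group. A group with 1 to 3 counts is given as a ratio with its 95% counting interval.

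The alternatives were DESeq2 size factors, upper-quartile factors, the DESeq2 test, no low-count filter, a filter of 1 CPM in 2 libraries, a fit of the libraries of the line alone, a block for replicate number, and each library left out in turn. Chosen after seeing the data were a correction for transcript GC content (a lowess trend of span 0.3 per library over genes with a mean of at least 1 CPM, entered as offsets), the same in the libraries of a line alone, a fit of symbol-named genes alone, limma voom with a weight per group, and, for the overlap of the compounds within a line, a split of the 2 control libraries between the compounds. Counts were simulated from these libraries with 100 genes changed 2-fold and 100 changed 4-fold, each up or down at random. On these, edgeR on all libraries tested 25371 genes. For A375 with 6-thio-dG it found 12 of the 2-fold and 51 of the 4-fold changes and called 36 unchanged genes, where DESeq2 found 52 and 86 and called 570 unchanged genes among 29042. For LOX-IMVI BR with 6-thio-dG it found 0 by edgeR (5 by DESeq2) of the 2-fold and 59 (94 by DESeq2) of the 4-fold changes and called 0 unchanged genes (0 by DESeq2). A fit of the line alone found 2 and 21 in A375 with 1 unchanged gene called among 21904 genes, and 100 and 99 in LOX-IMVI BR with 22 unchanged genes called among 20860 genes. The spread shared by all libraries is thus too small for A375 (coefficient of biological variation 36.1% within the line, 25.8% in the shared fit). It is larger than that between the LOX-IMVI BR replicates (4.55%). In A375 with 6-thio-dG, simulated counts of 13666 genes with a GC trend gave 15 calls among unchanged genes without and 56 with GC correction, and 16 and 68 of 172 changed genes were called. In simulated counts of LOX-IMVI BR with 6-thio-dG, over 29114 genes, limma camera called a raised list (adjusted p = 2.06e-23) and none of 30 random lists. The simulated genes were drawn independently of each other, so this could not test the preset correlation.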

Results

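Gene expression was measured in A375 and LOX-IMVI BR, 2 human metastatic melanoma cell lines, under a control and 2 compounds directed at telomerase. One compound, 6-thio-dG, is a thioguanine deoxynucleoside that telomerase can add to telomeres. The other, BIBR1532, is a small-molecule telomerase inhibitor. Each of the 6 groups held 2 libraries. In A375 the control libraries held 25822381 and 14817553 counts, the 6-thio-dG libraries 11813388 and 12151180, and the BIBR1532 libraries 21692316 and 19546597. In LOX-IMVI BR the totals were 22700404 and 24503867 in the control, 20941572 and 24818133 with 6-thio-dG, and 15659238 and 23097771 with BIBR1532. NONCODE genes took 4.54 ± 0.104% of counts in the LOX-IMVI BR control and 7.29 ± 0.179% with 6-thio-dG. In A375 these shares were 5.31 ± 1.26% and 7.04 ± 0.366%. Values are mean ± SD of 2 libraries throughout. The samples are biological replicates per the labels. The p-values rest on a spread shared by both lines (25.8%), not on that of the replicates compared. It is too small for A375 (36.1%) and larger than that between the LOX-IMVI BR replicates (4.55%). The median chi-square per gene between replicates there was 0.61 (control), 0.698 (6-thio-dG) and 1.227 (BIBR1532), against 0.455 from counting error alone. Whether so small a spread covers variation between separate cultures cannot be told. Fits of LOX-IMVI BR alone rest on it.

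Replicates lay close in LOX-IMVI BR and further apart in A375. The median absolute log2 difference between replicates was 0.063, 0.08 and 0.116 in LOX-IMVI BR for control, 6-thio-dG and BIBR1532. In A375 it was 0.556, 0.589 and 0.159. The A375 6-thio-dG libraries differed along transcript GC content. Removing a GC trend from each library lowered their difference to 0.295 and raised their correlation across genes from 0.897 to 0.96. For the A375 control the difference fell to 0.474, which left it the largest among the groups. Control replicate 2, the shallower one, had 34297 genes with a count, against 41760 in replicate 1. Its 10 most abundant genes took 8.781% of counts against 5.196%, and its TMM factor was 0.746 against 1.037. Each comparison of A375 with its control uses this pair, and the cause of its spread was not tested. The GC trend also differed between groups and between the lines. In the eighth of genes lowest in GC the median log2 deviation was −0.164 and −0.221 in the A375 controls. It was −1.476 and −1.146 with BIBR1532 in A375, and 0.901 and 0.91 in the LOX-IMVI BR controls.

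**Figure D1:**
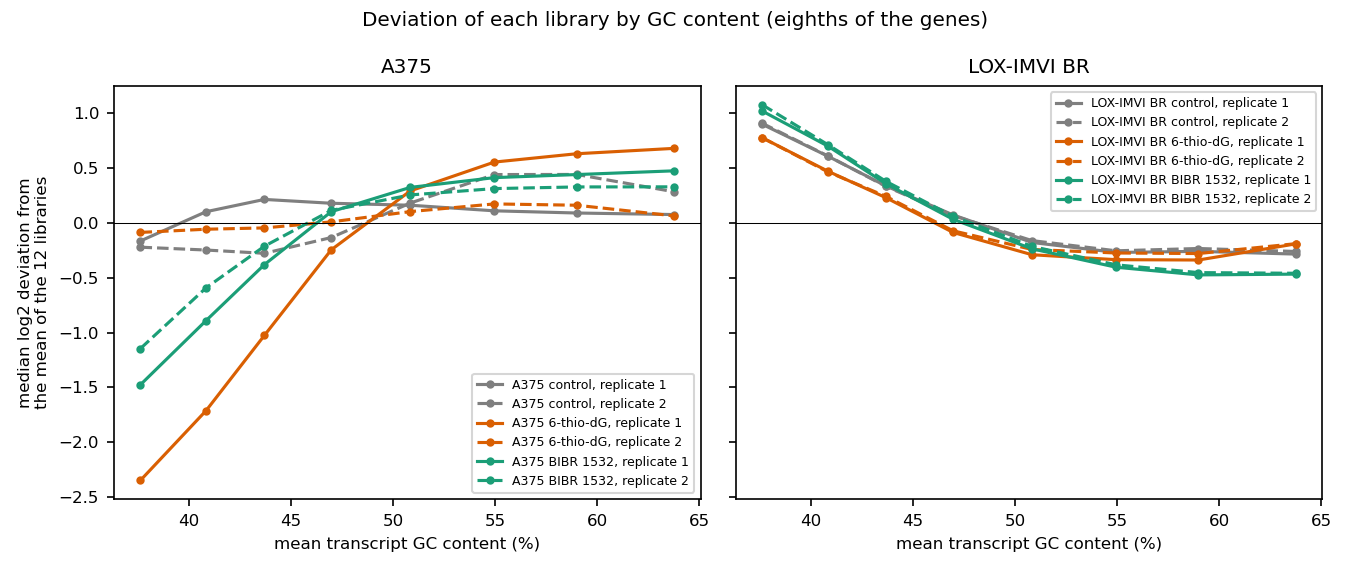
Median log2 deviation of each library from the mean of the 12 libraries (vertical axis) for genes grouped into eighths of transcript GC content (horizontal axis, %), with A375 and LOX-IMVI BR in separate panels and 1 line per library. The A375 6-thio-dG libraries take different slopes, while the replicates of each LOX-IMVI BR group run close together.

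The first comparison asked how A375 responded to 6-thio-dG. PLK1, a kinase of mitotic entry, fell from 76.3 ± 15 to 19.2 ± 3.62 CPM, and the spindle checkpoint kinase gene BUB1B from 30.5 ± 6.08 to 3.64 ± 3.02 CPM. MYC fell from 426 ± 65.9 to 23 ± 6.95 CPM (log2 fold change −4.21 ± 0.32, adjusted p = 8.68e-06). AXL, a receptor tyrosine kinase of dedifferentiated melanoma, fell from 1520 ± 175 to 250 ± 62.5 CPM. The inducible chaperone HSPA1A rose from 9.74 ± 3.51 to 195 ± 42.1 CPM, the constitutive chaperone HSPA8 from 839 ± 207 to 5080 ± 166 CPM and HMOX1, heme oxygenase, from 10.3 ± 4.61 to 85.6 ± 8.76 CPM. HSPA1A and HSPA1B are near-identical copies, so their separate levels are uncertain. By edgeR 5261 genes were called, 2871 higher and 2390 lower. Among the symbol-named genes 1127 were higher and 1866 lower.

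The mitosis list fell in 36 of 45 members over all genes and in 43 adjusted over the list alone (camera adjusted p = 4.43e-21; adjusted p = 0.113 with an estimated correlation). Of 44 genes of the ATF4 and unfolded protein response 28 fell, and 33 adjusted over the list alone (camera adjusted p = 9.3e-16; adjusted p = 0.113 with an estimated correlation). HSPA5, the main chaperone of the endoplasmic reticulum, went from 3300 ± 352 to 916 ± 19.6 CPM, and ASNS, asparagine synthetase, from 976 ± 517 to 146 ± 0.555 CPM. Ribosome biogenesis and MYC targets fell in 12 of 40 members, and in 25 adjusted over the list alone (camera adjusted p = 8.03e-09; adjusted p = 0.113 with an estimated correlation). ODC1, the first enzyme of polyamine synthesis, fell from 491 to 109 CPM. Cytosolic ribosomal proteins fell in 8 of 37 members, and adjusted over the list alone 14 fell and 1 rose (camera adjusted p = 0.000592; adjusted p = 0.605 with an estimated correlation). Purine genes fell in 12 of 33, and adjusted over the list alone 16 fell and 1 rose (camera adjusted p = 2.71e-06; adjusted p = 0.113 with an estimated correlation). Among them NT5E, an ecto-nucleotidase, went from 223 to 32.8 CPM.

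Dedifferentiated melanoma genes fell in 13 of 29 members, and in 16 adjusted over the list alone. TNC, tenascin, went from 1220 ± 31.3 to 149 ± 59.4 CPM and the collagen crosslinking enzyme LOXL2 from 140 ± 75.8 to 15.7 ± 2.88 CPM. This was the 1 list whose call held with an estimated correlation (camera adjusted p = 8.79e-10; adjusted p = 0.0101 with an estimated correlation). ERK pathway output fell in 14 of 24 members, and in 16 adjusted over the list alone (camera adjusted p = 6.01e-07; adjusted p = 0.113 with an estimated correlation). DUSP6, a phosphatase of ERK, went from 289 ± 25.7 to 85 ± 10.3 CPM. In the extracellular matrix list 16 of 40 members fell and 1 rose, and 17 and 1 adjusted over the list alone (camera adjusted p = 8.49e-06; adjusted p = 0.17 with an estimated correlation). Its collagen gene COL4A2 went from 449 ± 133 to 60 ± 25.2 CPM. Secreted inflammatory factors fell in 17 of 41 members and rose in 5, and in 19 and 7 adjusted over the list alone (camera adjusted p = 0.00396; adjusted p = 0.462 with an estimated correlation). The cytokine gene IL11 went from 872 ± 120 to 51.5 ± 23.8 CPM.

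NRF2 targets rose in 12 of 30 members and fell in 2, and in 13 and 2 adjusted over the list alone (camera adjusted p = 0.000346; adjusted p = 0.268 with an estimated correlation). GCLM, of glutathione synthesis, went from 7.54 to 45.5 CPM, and the ferritin chain FTH1 from 611 ± 53.1 to 2450 ± 964 CPM. Heat shock genes rose in 7 of 22 members, and adjusted over the list alone 7 rose and 1 fell (camera adjusted p = 0.0171; adjusted p = 0.473 with an estimated correlation). Leukocyte marker genes rose in 6 of 10 tested members, and in 6 adjusted over the list alone (camera adjusted p = 0.000884; adjusted p = 0.113 with an estimated correlation). Among these the actin-bundling gene LCP1 went from 2.74 to 20 ± 10.7 CPM. DNA repair genes fell in 8 of 44, and in 10 adjusted over the list alone (camera adjusted p = 7.75e-07, and adjusted p = 0.268 with an estimated correlation). GC correction moved their median log2 fold change from −0.825 to −0.308. In the A375 libraries alone 1 DNA repair, 1 ribosome biogenesis, 1 ribosomal protein, 1 purine and 0 replication genes were called lower. Of the mitosis, ATF4 and dedifferentiated melanoma genes 13, 11 and 11 were lower there.

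In the telomerase and shelterin list 6 of 28 members fell and 1 rose, and 8 and 2 adjusted over the list alone, but with upper-quartile factors 2 were lower and 3 higher. DKC1, which encodes a protein of the telomerase complex, fell from 552 ± 33.1 to 179 ± 24.6 CPM. In the replication list 11 of 48 fell and 1 rose, and 12 and 1 adjusted over the list alone, but with upper-quartile factors 3 were lower and 7 higher. The camera adjusted p of these lists were 0.0284 and 0.00359 (adjusted p = 0.212 and adjusted p = 0.369 with an estimated correlation). After GC correction the camera p of the telomerase and shelterin, replication and secreted factor lists were 0.199, 0.187 and 0.0858.

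The other 16 lists were not called. Counts of members called higher and lower are given over all genes, and in brackets adjusted over the list alone, followed by the camera adjusted p. They were 9 and 4 (11 and 4) of 43 p53 targets with 0.259, 4 and 3 (4 and 3) of 23 histones with 0.71, and 4 and 2 (4 and 2) of 41 interferon-stimulated genes with 0.892. Apoptosis regulators had 4 and 6 (5 and 9) of 32 with 0.651, hypoxia genes 2 and 9 (3 and 10) of 40 with 0.107, and oxidative phosphorylation 1 and 2 (1 and 2) of 37 with 0.0529. Aryl hydrocarbon receptor targets had 2 and 1 (2 and 1) of 9 with 0.71, melanocyte genes 3 and 9 (5 and 9) of 24 with 0.0519, and autophagy and lysosome genes 7 and 1 (9 and 1) of 35 with 0.0639. Fibroblast markers had 1 and 2 (1 and 2) of 11 with 0.33, their median lying above 0 and their mean and test below. Endothelial markers had 4 and 3 (4 and 3) of 9 with 0.892, their median and mean lying above 0 and the test pointing down. Of 26 cholesterol genes 1 was higher and 2 were lower over all genes (0.349), a count not kept when adjusted over the list alone. Of 18 fatty acid synthesis genes 4 were lower, and adjusted over the list alone 4 were lower and 2 higher (0.0604). Keratinocyte markers were higher in 2 of 12, by either adjustment (0.465). No member passed by edgeR among 4 metallothioneins (0.325) and 6 epithelial markers (0.281), nor by DESeq2, with 1 of each higher at an unadjusted p under 0.05. After GC correction camera called p53 targets (0.00162), interferon-stimulated genes (0.0354) and autophagy and lysosome genes (0.00124) upward.

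Among the largest single rises in A375, the placental phosphatase gene ALPP went from 0.267 to 51.8 ± 25.3 CPM (log2 fold change 7.57 ± 0.57, adjusted p = 1.15e-05). GCNT3, without counts in the control, was at least 85.3-fold higher at 6.73 CPM. Among the largest falls, CD274, the gene of the immune checkpoint ligand PD-L1, went from 229 ± 124 to 6.08 ± 2.23 CPM and the potassium channel gene KCNH1 from 108 ± 7.77 to 3.72 ± 0.993 CPM. CDKN1A, the p21 cell cycle inhibitor, rose from 264 ± 121 to 759 ± 264 CPM (adjusted p = 0.00829), but not in the A375 libraries alone (adjusted p = 0.0726). MITF, the melanocyte master regulator, fell from 40 ± 7.83 to 8.55 ± 7.95 CPM (log2 fold change −2.22 ± 0.50, adjusted p = 0.00889). The MITF call was lost in the A375 libraries alone (0.0778) and without control replicate 1 (0.0626), and its log2 change was −1.51 and −3.79 without 6-thio-dG replicate 1 and replicate 2. TERT, the catalytic subunit of telomerase, was at 6.68 ± 3.94 and 3.19 ± 2.23 CPM (adjusted p = 0.105), MDM2 at 95.8 ± 48.8 and 191 ± 135 CPM (0.129) and GDF15 at 1100 ± 579 and 668 ± 232 CPM (0.171). With GC correction these 3 passed (0.0242, 0.00148 and 0.0114). Before it their libraries overlapped: TERT was at 9.46 and 3.89 CPM in the controls and 4.76 and 1.61 CPM with 6-thio-dG. MDM2 was at 130 and 61.3 against 95 and 286 CPM, and GDF15 at 687 and 1510 against 832 and 504 CPM. In simulated counts of this comparison GC correction called 56 unchanged genes beside 68 changed ones, so these 3 calls are uncertain. Upper-quartile factors shifted the median of all genes by 0.386 on the log2 scale. The share of called genes that were higher moved from 54.6% to 80%. A fit of symbol-named genes alone shifted the median of those genes by 0.16 and moved their share from 37.7% to 53.6%. The share of all called genes was 37.7% by the DESeq2 test and 33% without a filter. It was 21.7% with voom and group weights, which called 290 genes. The A375 libraries alone gave 1227 called genes, 13 of them mitosis genes that fell, and leaving out 6-thio-dG replicate 2 gave 10233.

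The next comparison asked how A375 responded to BIBR1532. The inflammatory cytokine gene IL1B rose from 3.47 ± 0.208 to 290 ± 16.7 CPM (log2 fold change 6.38 ± 0.35, adjusted p = 3.26e-07), and CSF2, which encodes GM-CSF, from 5.72 ± 0.272 to 400 ± 29.1 CPM. CYP1A1, the standard target of the aryl hydrocarbon receptor, rose from 4.22 ± 1.21 to 139 ± 7.83 CPM (adjusted p = 8.13e-06). FN1, fibronectin, rose from 57.9 ± 30.6 to 357 ± 13.1 CPM, whereas MYC fell from 426 ± 65.9 to 90.9 ± 2.27 CPM. By edgeR 4594 genes were called, 2473 higher and 2121 lower. Among symbol-named genes 1293 were higher and 1481 lower.

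Secreted inflammatory factors rose in 25 of 41 members and fell in 3, and in 27 and 3 adjusted over the list alone (camera adjusted p = 1.6e-13; adjusted p = 0.169 with an estimated correlation). SERPINB2, a protease inhibitor of this list, rose from 0.605 ± 0.169 to 49.2 ± 2.09 CPM. Aryl hydrocarbon receptor targets rose in 5 of 9, and in 5 adjusted over the list alone (camera adjusted p = 0.00281; adjusted p = 0.169 with an estimated correlation). Ribosome biogenesis and MYC targets fell in 19 of 40, and in 25 adjusted over the list alone (camera adjusted p = 1.65e-09; adjusted p = 0.169 with an estimated correlation). Ribosomal proteins fell in 14 of 37, and in 24 adjusted over the list alone (camera adjusted p = 8.47e-08, and adjusted p = 0.492 with an estimated correlation). In the A375 libraries alone 0 ribosome biogenesis genes and 1 ribosomal protein gene were called lower. NPM1, a nucleolar chaperone, fell from 335 ± 117 to 77.2 ± 11.5 CPM. Its call was lost in the A375 libraries alone (adjusted p = 0.08) and without control replicate 2 (0.118), BIBR1532 replicate 1 (0.137) or replicate 2 (0.119).

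Mitosis genes fell in 17 of 45 and rose in 1, and in 19 and 2 adjusted over the list alone (camera adjusted p = 0.000259; adjusted p = 0.499 with an estimated correlation). DNA repair genes fell in 7 of 44, and in 13 adjusted over the list alone (camera adjusted p = 0.00152, and adjusted p = 0.494 with an estimated correlation). In the A375 libraries alone, where 134 genes were called lower, 0 mitosis and 0 DNA repair genes fell. GC correction moved the median log2 fold change from −0.752 to −0.358 for mitosis and from −0.952 to −0.353 for DNA repair. In the p53 list 9 of 43 rose and 2 fell, and 15 and 4 adjusted over the list alone (camera adjusted p = 0.00635; adjusted p = 0.376 with an estimated correlation), with the phosphatase gene INPP5D going from 2.12 to 19.1 CPM. Interferon-stimulated genes rose in 9 of 41 and fell in 2, and in 11 and 3 adjusted over the list alone (camera adjusted p = 0.0152; adjusted p = 0.449 with an estimated correlation). The antiviral gene OAS2 went from 3.27 to 19.1 CPM. Extracellular matrix genes rose in 13 of 40 and fell in 2, and in 14 and 4 adjusted over the list alone (camera adjusted p = 0.00519; adjusted p = 0.449 with an estimated correlation). TIMP3, a metalloprotease inhibitor, went from 377 to 1550 CPM.

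Camera also called ERK output (3 higher and 1 lower; adjusted p = 0.0471), the ATF4 response (2 higher and 9 lower; 0.0233) and oxidative phosphorylation (2 lower; 0.00663) in this comparison. Adjusted over the list alone these counts were 3 and 1, 3 and 11, and 1. The telomerase and shelterin list (1 higher and 6 lower; 0.0233) and epithelial markers (2 of 6 higher; 0.043) were called as well, with 2 and 9, and 3, adjusted over the list alone. In the order given these 5 lists had adjusted p = 0.494, adjusted p = 0.571, adjusted p = 0.719, adjusted p = 0.376 and adjusted p = 0.492 with an estimated correlation. After GC correction DNA repair (0.0549) and epithelial markers (0.0874) were not called, and NRF2 targets (0.0391) and melanocyte genes (0.0348) were called upward. Of the 17 lists not called, leukocyte markers (0.0536, 3 higher), NRF2 targets (0.0539, 5 higher and 1 lower) and purine genes (0.0733, 2 higher and 2 lower) had the lowest p. Adjusted over the list alone these counts were 4, 5 and 1, and 2 and 1.

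The largest rises with BIBR1532 in A375 included genes of repeated families. LCE1F, of the cornified envelope, rose from 0.432 ± 0.0293 to 50.7 ± 6.14 CPM and the ubiquitin-like gene UBD from 0.173 to 17.9 CPM. PRAMEF1, with 2 counts in the control, was 157-fold higher (95% counting interval 43.2 to 1300). LCE and PRAMEF genes have close copies, so the assignment of their reads is uncertain. Among the falls, KCNH1 went from 108 ± 7.77 to 4.32 ± 0.535 CPM (adjusted p = 2.21e-06), BDNF, a neurotrophin, from 48.5 ± 2.21 to 5.29 ± 0.818 CPM and the cadherin gene CDH4 from 20.9 ± 4.36 to 0.971 CPM. CDKN1A rose to 622 ± 42.6 CPM (adjusted p = 0.0256) and MITF fell to 8.05 ± 2.26 CPM (adjusted p = 0.00825). Neither passed in the A375 libraries alone (0.149 and 0.0813), without control replicate 1 (0.062 and 0.058), without BIBR1532 replicate 1 (0.173 and 0.119) or without BIBR1532 replicate 2 (0.0999 and 0.0854). AXL at 1160 ± 46.6 CPM (adjusted p = 0.329), TERT at 5.69 ± 0.0496 CPM (0.719), MDM2 at 106 ± 23.5 CPM (0.848) and GDF15 at 516 ± 34.4 CPM (0.0502) were not called. With GC correction AXL (0.0215), MDM2 (0.0408) and GDF15 (0.00267) passed. The MDM2 libraries overlapped before it, at 130 and 61.3 CPM in the controls and 89.8 and 123 CPM with BIBR1532. Upper-quartile factors shifted the median of all genes by 0.232 on the log2 scale and moved the share of called genes that were higher from 53.8% to 66.4%, and among symbol-named genes fitted alone the share went from 46.6% to 64.6%. The A375 libraries alone gave 924 called genes, 790 higher and 134 lower, and leaving out BIBR1532 replicate 1 or replicate 2 gave 937 (846 and 91) and 984 (875 and 109), whereas voom with group weights gave 979 higher and 1965 lower.

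In LOX-IMVI BR the same question was asked of 6-thio-dG. PLK1 fell from 238 ± 0.0511 to 16 ± 1.05 CPM (log2 fold change −3.90 ± 0.31, adjusted p = 4.61e-06) and CCNB1, cyclin B1, from 152 ± 6.68 to 13.8 ± 0.654 CPM. CDKN1A rose from 53 ± 2.29 to 272 ± 5.6 CPM (adjusted p = 0.000496) and the stress cytokine GDF15 from 43.6 ± 0.937 to 347 ± 12 CPM (0.000158). COL1A1, a main fibrillar collagen, fell from 1630 ± 16.2 to 15.5 ± 0.609 CPM (log2 fold change −6.72 ± 0.40, adjusted p = 1.16e-06) and COL3A1 from 151 ± 3.81 to 2.02 CPM. The hypoxia-inducible genes VEGFA, which encodes an angiogenic growth factor, and DDIT4 fell from 257 ± 4.36 to 13.5 ± 0.97 CPM and from 360 ± 10.9 to 11 ± 0.306 CPM. By edgeR 4939 genes were called, 2855 higher and 2084 lower. Among symbol-named genes 897 were higher and 1554 lower.

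Of 45 mitosis genes 42 fell, and 44 adjusted over the list alone (camera adjusted p = 1.21e-34; adjusted p = 0.036 with an estimated correlation). Of 48 replication genes 20 fell, and 29 adjusted over the list alone (camera adjusted p = 1.69e-14; adjusted p = 0.036 with an estimated correlation). RRM2, a ribonucleotide reductase subunit, went from 293 to 89.9 CPM and MCM4, of the replicative helicase, from 502 to 159 CPM. In the p53 list 19 of 43 rose, and adjusted over the list alone 24 rose and 1 fell (camera adjusted p = 2.56e-09; adjusted p = 0.0254 with an estimated correlation). Hypoxia and glycolysis genes fell in 30 of 40 and rose in 1, and in 33 and 1 adjusted over the list alone (camera adjusted p = 5.77e-22; adjusted p = 0.0254 with an estimated correlation). CA9, a carbonic anhydrase, went from 18.4 ± 0.635 to 0.149 ± 0.0159 CPM. In the extracellular matrix list 21 of 40 fell and 2 rose, and 23 and 2 adjusted over the list alone (camera adjusted p = 9.52e-16; adjusted p = 0.0254 with an estimated correlation). Fibroblast markers fell in 7 of 11, and in 8 adjusted over the list alone (camera adjusted p = 3.11e-09; adjusted p = 0.0102 with an estimated correlation). They include the growth factor receptor PDGFRA, which went from 56.1 to 5.11 CPM, and the protease gene FAP, which went from 70.8 to 12.7 CPM. Fatty acid synthesis genes fell in 9 of 18, and in 13 adjusted over the list alone (camera adjusted p = 2.56e-09; adjusted p = 0.0102 with an estimated correlation). SCD, a fatty acid desaturase, went from 1500 ± 42.3 to 173 ± 0.982 CPM. Dedifferentiated melanoma genes fell in 14 of 29 and rose in 2, and in 14 and 2 adjusted over the list alone (camera adjusted p = 3.32e-05; adjusted p = 0.0254 with an estimated correlation). WNT5A, a noncanonical WNT ligand, went from 484 to 101 CPM.

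Secreted inflammatory factors fell in 24 of 41 and rose in 5, and in 25 and 6 adjusted over the list alone (camera adjusted p = 2.56e-09; adjusted p = 0.102 with an estimated correlation). IL6 fell from 28.7 to 1.93 CPM while the matrix metalloprotease MMP3 rose from 2.56 ± 0.212 to 50.7 ± 1.47 CPM. Interferon-stimulated genes fell in 11 of 41, and in 12 adjusted over the list alone (camera adjusted p = 5.44e-07; adjusted p = 0.0693 with an estimated correlation). Cholesterol synthesis genes fell in 8 of 26 and rose in 2, and in 10 and 2 adjusted over the list alone (camera adjusted p = 4.22e-05; adjusted p = 0.101 with an estimated correlation). DNA repair genes fell in 13 of 44, and in 15 adjusted over the list alone (camera adjusted p = 9.23e-08; adjusted p = 0.202 with an estimated correlation). The ATF4 and unfolded protein response list moved both ways, with 12 of 44 lower and 8 higher, and 16 and 8 adjusted over the list alone (camera adjusted p = 0.00925; adjusted p = 0.512 with an estimated correlation). HSPA5 fell from 2220 ± 68.5 to 396 ± 12.4 CPM and SLC3A2, an amino acid transporter subunit, rose from 190 to 1340 ± 21.1 CPM. Camera also called purine genes (2 of 33 lower, 1 adjusted over the list alone; 0.0107) and metallothioneins (2 of 4 higher, 3 adjusted over the list alone; 0.00263). These had adjusted p = 0.198 and adjusted p = 0.0557 with an estimated correlation. After GC correction, which keeps symbol-named genes alone, the ATF4 list (0.313) and the purine list (0.463) were not called. NRF2 targets (0.014) were called upward. The medians of these 3 lists with GC correction were −0.152, −0.316 and 0.511. A fit of symbol-named genes without it gave nearly the same, −0.142, −0.339 and 0.507, against −0.328, −0.525 and 0.321 over all genes. The changed calls thus cannot be credited to GC content rather than to the smaller set of genes.

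Among the largest single changes in LOX-IMVI BR, the nucleotide receptor gene P2RY6 fell from 53.4 ± 1.01 to 0.172 ± 0.097 CPM (log2 fold change −8.26 ± 0.51, adjusted p = 1.16e-06). The hormone gene STC1 fell from 244 ± 2.53 to 2.45 CPM, and GUCA1B, a guanylate cyclase activator, rose from 1.18 to 21.4 CPM. MDM2, a p53 target, rose from 106 ± 2.33 to 478 ± 5.81 CPM (adjusted p = 0.0048), though not without control replicate 1 (0.0613) or control replicate 2 (0.0586). AXL fell from 435 ± 10.6 to 207 ± 5.03 CPM (adjusted p = 0.0129), though not with upper-quartile factors (0.098), without control replicate 1 or 2 (0.104 and 0.0874) or without 6-thio-dG replicate 1 or 2 (0.138 and 0.109). TERT was at 10.6 ± 1.9 and 12.8 ± 0.213 CPM (adjusted p = 0.733, and 0.0323 in the LOX-IMVI BR libraries alone) and MITF was not called (0.857). Upper-quartile factors shifted the median of all genes by 0.23 on the log2 scale. The share of called genes that were higher moved from 57.8% to 73.5%. A fit of symbol-named genes alone shifted the median of those genes by 0.185 and moved their share from 36.6% to 49.2%. The share of all called genes was 44.9% by the DESeq2 test. The LOX-IMVI BR libraries alone gave 15119 called genes, 7708 higher and 7411 lower, voom with group weights gave 16517, and leaving out control replicate 1 or 2 or 6-thio-dG replicate 1 or 2 gave 1614, 1550, 1764 and 1864.

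With BIBR1532 in LOX-IMVI BR the cytokine gene CSF2 rose from 0.187 ± 0.122 to 21.7 ± 10.9 CPM (log2 fold change 6.79 ± 0.57, adjusted p = 4.4e-05), IL6 from 28.7 to 437 ± 167 CPM and PTX3, a secreted pattern recognition protein, from 31.1 ± 1.25 to 1230 ± 586 CPM. CHAC1, a glutathione-degrading enzyme, rose from 4.15 to 73.6 ± 6.98 CPM and the stress transcription factor DDIT3 from 39.4 to 309 ± 18.6 CPM. The hypoxia-inducible gene NDRG1 fell from 295 ± 16.1 to 33 ± 0.531 CPM (adjusted p = 0.000281) and the constitutive chaperone HSPA8 from 4710 ± 128 to 611 ± 190 CPM (9.92e-05). CA9, at 18.4 CPM in the control and 3 counts with BIBR1532, was 220-fold lower (95% counting interval 75 to 1070). By edgeR 1046 genes were called, 845 higher and 201 lower. Among symbol-named genes 438 were higher and 108 lower.

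Secreted inflammatory factors rose in 20 of 41 and fell in 2, and in 25 and 3 adjusted over the list alone (camera adjusted p = 4.27e-14; adjusted p = 0.0738 with an estimated correlation). TNFAIP3, a feedback inhibitor of NF-kappaB, went from 75 to 628 ± 254 CPM. The ATF4 and unfolded protein response list rose in 17 of 44 and fell in 2, and in 21 and 4 adjusted over the list alone (camera adjusted p = 2.41e-06; adjusted p = 0.214 with an estimated correlation). Of 43 p53 targets 11 rose, and 20 adjusted over the list alone, among them GADD45A to 526 ± 136 CPM and GDF15 to 307 ± 46.9 CPM. This list kept its call (camera adjusted p = 4.54e-12, and adjusted p = 0.0491 with an estimated correlation). SESN2, which rose from 37.9 to 327 CPM, belongs to both the p53 and the ATF4 list, so the 2 calls are not independent. The p53 targets CDKN1A and MDM2 were not called by edgeR (adjusted p = 0.154 and 0.311). ERK pathway output rose in 9 of 24, and adjusted over the list alone 13 rose and 1 fell (camera adjusted p = 1.38e-09; adjusted p = 0.0729 with an estimated correlation). EGR1, an immediate early gene, went from 11.8 to 281 ± 133 CPM. Hypoxia and glycolysis genes fell in 11 of 40 and rose in 2, and in 20 and 2 adjusted over the list alone (camera adjusted p = 8.01e-17; adjusted p = 0.068 with an estimated correlation). Heat shock genes fell in 4 of 22, and in 5 adjusted over the list alone (camera adjusted p = 2.66e-06; adjusted p = 0.179 with an estimated correlation).

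Mitosis genes were called by camera as higher in this comparison (median log2 fold change 0.67, camera adjusted p = 7.85e-08; adjusted p = 0.307 with an estimated correlation). No member of the mitosis (45), replication (48), DNA repair (44) and ribosomal protein (37) lists passed by edgeR in the shared fit, over all genes or adjusted over the list alone. At an unadjusted p under 0.05, 9 mitosis, 3 replication and 8 DNA repair genes were higher and 17 ribosomal protein genes lower. The DESeq2 test called 3 mitosis, 2 replication and 1 DNA repair gene higher and 2 ribosomal protein genes lower. In the LOX-IMVI BR libraries alone, where 10802 of 24087 genes were called, 42 mitosis genes were higher and 1 lower. There 27 replication genes were higher and 8 lower, 26 DNA repair genes higher and 5 lower, and 33 ribosomal protein genes lower. Camera called replication (0.0392) and DNA repair (0.00764) upward and ribosomal proteins downward (3.85e-11), with adjusted p = 0.535, adjusted p = 0.562 and adjusted p = 0.307 with an estimated correlation. Also called were dedifferentiated melanoma genes (3 higher and 1 lower; 0.0019), aryl hydrocarbon receptor targets (1 higher; 0.00683) and metallothioneins (2 higher; 0.000521). Adjusted over the list alone these were 8 and 1, 1, and 2, and they had adjusted p = 0.068, adjusted p = 0.0906 and adjusted p = 0.068 with an estimated correlation. The extracellular matrix list (3 lower; 0.000353) and fibroblast markers (1 lower; 0.00945) were called downward, with 5 and 3 lower adjusted over the list alone. They had adjusted p = 0.214 and adjusted p = 0.0934 with an estimated correlation. CDKN1A at 103 ± 10.9 CPM (adjusted p = 0.154), MDM2 at 206 ± 25 CPM (0.311), AXL at 847 ± 16 CPM (0.061), MITF at 20 ± 1.36 CPM (0.149) and TERT at 14.1 ± 0.224 CPM (0.732) were not called in the shared fit. In the LOX-IMVI BR libraries alone all 5 passed, upward, with adjusted p = 3.14e-13, 6.78e-13, 2.3e-15, 1.73e-11 and 0.0177 in this order. With GC correction on all libraries CDKN1A (0.00333), AXL (0.00138) and MITF (0.0108) passed. Upper-quartile factors shifted the median of all genes by −0.121 on the log2 scale. The LOX-IMVI BR libraries alone gave 10802 called genes, 5559 higher and 5243 lower, and with GC correction as well 3670 in each direction, voom with group weights gave 9397, and leaving out control replicate 1 or 2 or BIBR1532 replicate 1 or 2 gave 224, 209, 319 and 402.

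**Figure D2:**
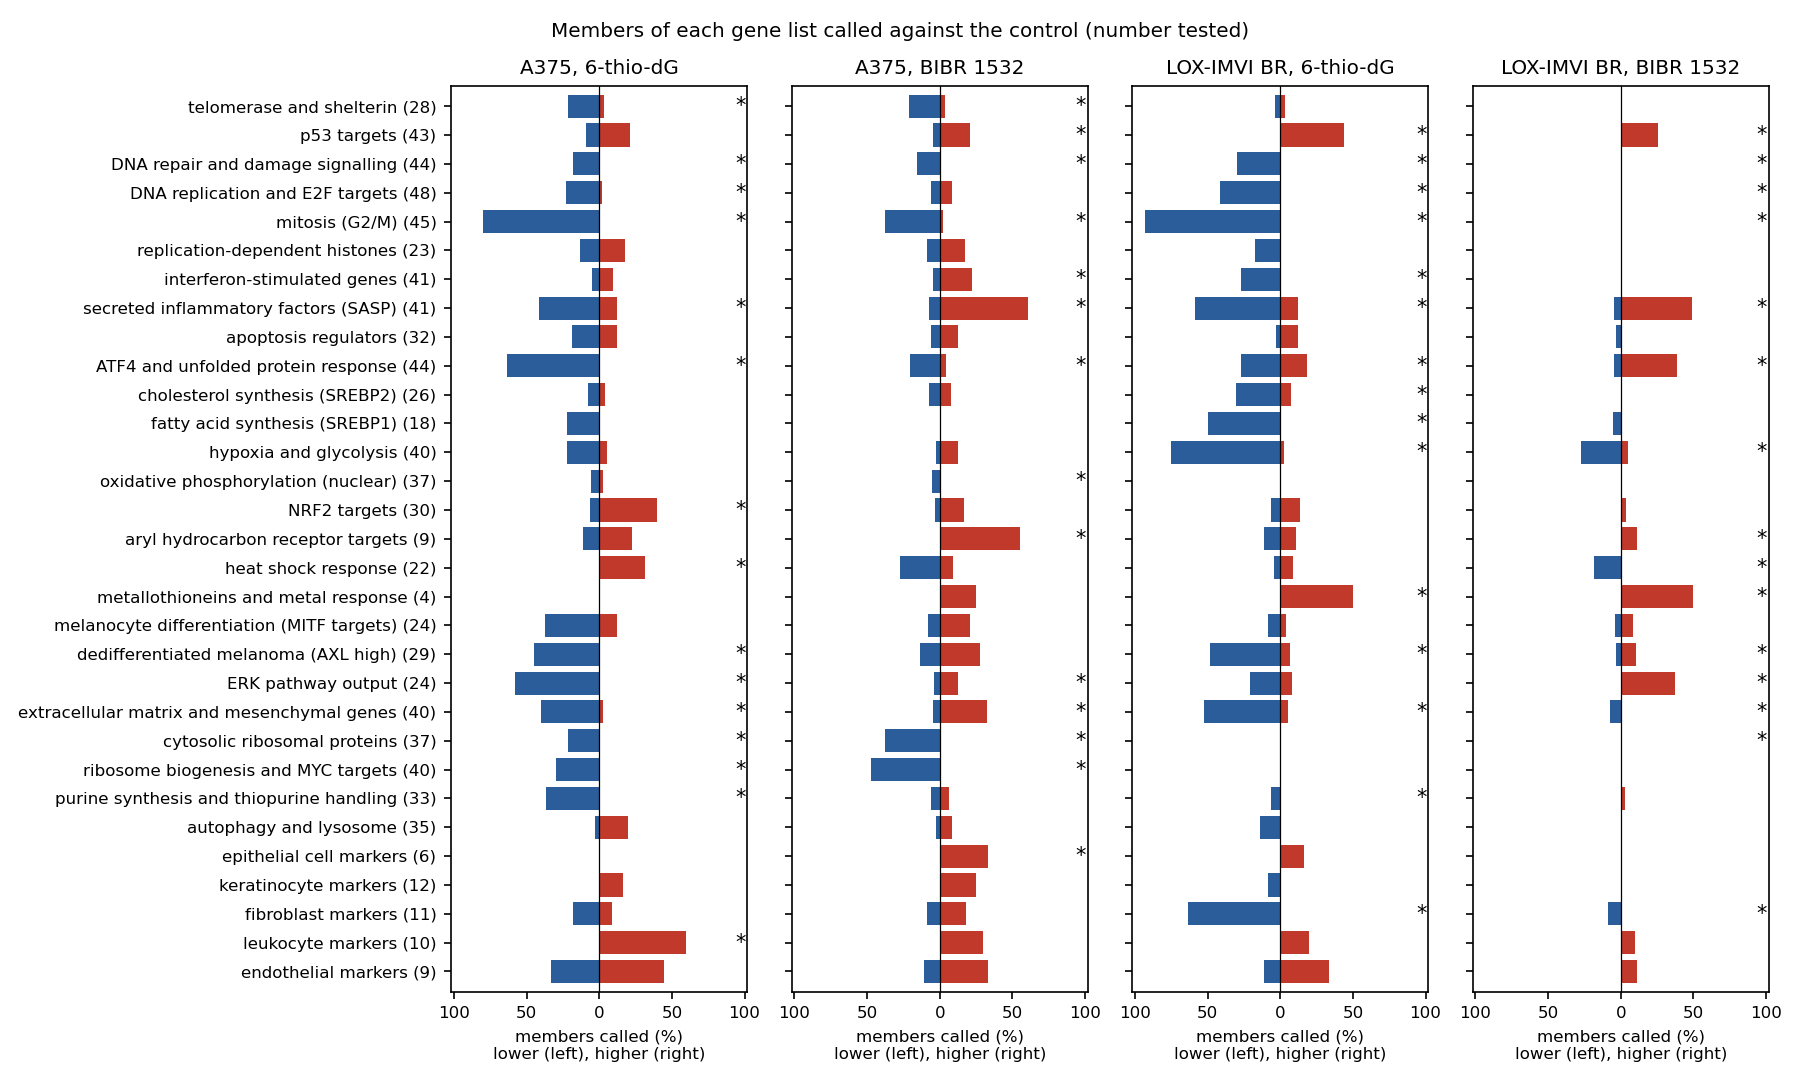
Percent of the tested members of each gene list called lower (left, blue) and higher (right, red) over all genes, for the 4 comparisons of a compound with its control, with the number of tested members in brackets and an asterisk where camera with the preset correlation called the list. Mitosis genes were lower with 6-thio-dG in both lines (36 and 42 of 45), and secreted inflammatory factors were higher with BIBR1532 in both lines (25 and 20 of 41).

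**Figure D3:**
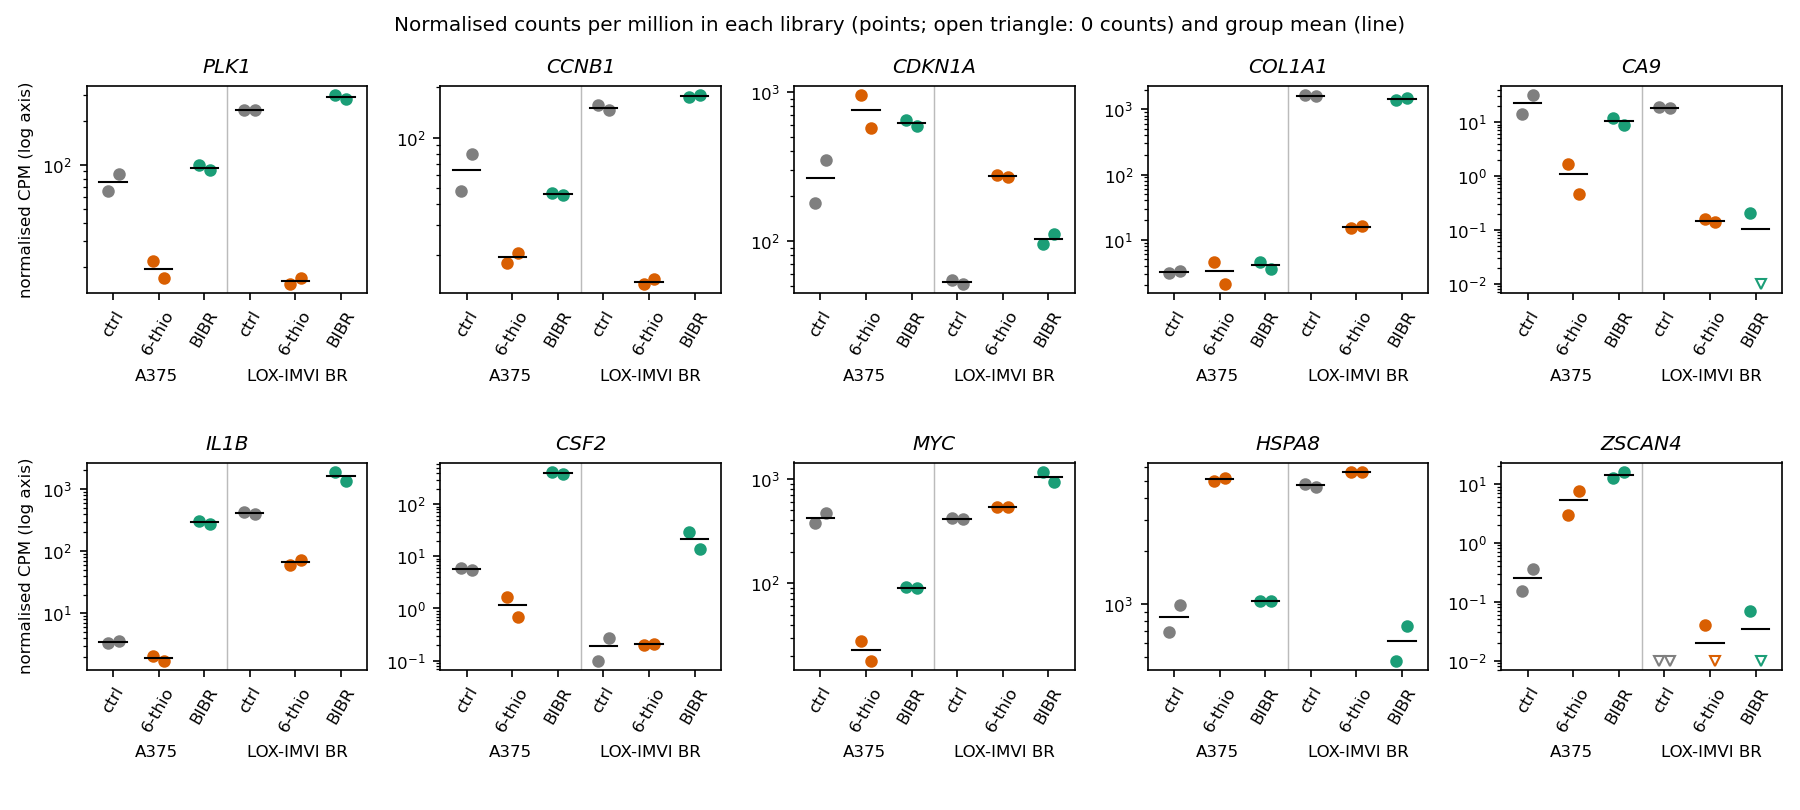
CPM (log axis) of 10 genes in each library by line and treatment, with points for libraries, lines for group means and open triangles, drawn at a fixed position, for libraries with 0 counts. PLK1 and CCNB1 fell with 6-thio-dG in LOX-IMVI BR, where COL1A1 fell from 1630 to 15.5 CPM, and IL1B in A375 rose from 3.47 to 290 CPM with BIBR1532.

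The compounds were also set against each other within each line. They were used at different concentrations, 5 µM for 6-thio-dG and 25 µM for BIBR1532, so the differences are those between these treatments. In A375 CSF2 was lower with 6-thio-dG than with BIBR1532, at 1.17 ± 0.706 against 400 ± 29.1 CPM (log2 fold change −8.44 ± 0.55, adjusted p = 5.86e-07), IL1B at 1.92 ± 0.242 against 290 ± 16.7 CPM, and the complement gene C3 at 5.22 ± 2.54 against 739 ± 59.7 CPM. Secreted inflammatory factors were lower in 30 of 41 and higher in 1, and in 32 and 1 adjusted over the list alone (camera adjusted p = 1.55e-23; adjusted p = 0.0356 with an estimated correlation). ERK output was lower in 16 of 24, and in 16 adjusted over the list alone (camera adjusted p = 2.77e-12; adjusted p = 0.0356 with an estimated correlation). Dedifferentiated melanoma genes were lower in 17 of 29, and adjusted over the list alone 19 were lower and 1 higher (camera adjusted p = 4.67e-11; adjusted p = 0.00749 with an estimated correlation). The calls of aryl hydrocarbon receptor targets (5 of 9 lower, 6 adjusted over the list alone; camera adjusted p = 0.000176) and melanocyte genes (11 lower and 2 higher of 24, 12 and 3 adjusted over the list alone; 0.000427) held as well, each with adjusted p = 0.0356 with an estimated correlation. Heat shock genes were higher with 6-thio-dG in 11 of 22, and in 14 adjusted over the list alone (camera adjusted p = 1.38e-07; adjusted p = 0.127 with an estimated correlation). By edgeR 4664 genes were called, 2115 higher and 2549 lower with 6-thio-dG. Upper-quartile and DESeq2 factors shifted the median of all genes by 0.159 and −0.113 on the log2 scale, and the share of called genes that were higher went from 45.3% to 60.1% and 36.6%, and to 29.9% by the DESeq2 test. The A375 libraries alone gave 1604 called genes, voom with group weights gave 1161, leaving out 6-thio-dG replicate 1 gave 8103 (55.1% higher), and leaving out BIBR1532 replicate 1 or 2 gave 1673 (28.8%) and 1944 (19.8%).

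In LOX-IMVI BR mitosis genes were lower with 6-thio-dG than with BIBR1532 in 44 of 45 members, and in 45 adjusted over the list alone (camera adjusted p = 2.01e-36; adjusted p = 0.0445 with an estimated correlation). Replication genes were lower in 31 of 48, and in 40 adjusted over the list alone (camera adjusted p = 9.4e-16; adjusted p = 0.0445 with an estimated correlation). IL6 was at 1.93 ± 0.398 against 437 ± 167 CPM (log2 fold change −7.82 ± 0.42, adjusted p = 2.61e-07) and PTX3 at 5.16 ± 0.657 against 1230 ± 586 CPM. Of the secreted factors 29 of 41 were lower and 3 higher, and the same numbers adjusted over the list alone (camera adjusted p = 2.65e-18; adjusted p = 0.0445 with an estimated correlation). Fatty acid synthesis (11 of 18 lower, camera adjusted p = 3.39e-08), dedifferentiated melanoma (20 lower and 1 higher of 29, 2.69e-09) and fibroblast marker genes (6 of 11 lower, 5.42e-06) kept their calls, with 13, 20 and 1, and 6 adjusted over the list alone. They had adjusted p = 0.0123, adjusted p = 0.0123 and adjusted p = 0.025 with an estimated correlation. MMP3 was higher with 6-thio-dG in both lines, at 5.44 ± 1.43 against 0.119 ± 0.105 CPM in A375 and at 50.7 ± 1.47 against 1.24 ± 0.567 CPM in LOX-IMVI BR. By edgeR 5999 genes were called, 2881 higher and 3118 lower with 6-thio-dG. Upper-quartile factors shifted the median of all genes by 0.352 on the log2 scale and moved the share of called genes that were higher from 48% to 69.5%, and for symbol-named genes alone it was 44.8% against 27.3% with a shift of 0.25, whereas the DESeq2 test gave 36.1%. The LOX-IMVI BR libraries alone gave 16112 called genes, voom with group weights gave 15811, and leaving out 6-thio-dG replicate 1 or 2 or BIBR1532 replicate 1 or 2 gave 2447, 2504, 2770 and 2448.

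The calls of the compounds overlapped within each line. In A375, 746 genes were called higher and 672 lower with both, against 244 and 174 if the calls were independent. Another 139 were called in opposite directions, and the log2 fold changes correlated across genes, which are not independent replicates, with r = 0.447. In LOX-IMVI BR the numbers were 202 higher, 110 lower (82.9 and 14.4 if independent) and 111 opposite, with r = 0.271. For opposite calls the number if independent was not computed, here or between the lines. The excess over independent calls therefore does not by itself measure agreement in direction. Both comparisons of a line share its 2 control libraries, which alone gives a correlation. In 20 simulations of unchanged groups against shared controls r averaged 0.489 in A375 and 0.505 in LOX-IMVI BR, with at most 1 gene called the same way in A375. The covariance of the fold changes exceeded the simulated one by 0.519 and 0.25. With 1 control library for each compound, so that none was shared, 850 and 691 genes were called the same way in A375 in the 2 possible splits (r = 0.272 and 0.159), and 382 and 233 in opposite directions. In LOX-IMVI BR these splits gave 55 and 50 the same way (r = 0.117 and 0.139), and 16 and 21 in opposite directions. In the A375 libraries alone 172 genes were called higher and 43 lower with both (24.4 and 2.71 if independent), and 22 in opposite directions. In the LOX-IMVI BR libraries alone 2005 were higher and 2881 lower, against 1780 and 1610 if independent, and 2689 in opposite directions (r = 0.19).

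Between the lines, 6-thio-dG gave 815 genes higher and 459 lower in both (282 and 171 if independent), 203 in opposite directions and r = 0.338 across genes, with no libraries shared. In the fits of each line alone 325 were higher and 208 lower in both (144 and 122 if independent), and 116 in opposite directions. The difference between the lines was called for 1612 genes, 721 with a higher log2 change in LOX-IMVI BR and 891 with a lower one. COL1A1 (difference in log2 change −6.79) and DDIT4 (−3.74) had lower changes in LOX-IMVI BR, and GDF15 (3.70) a higher one. CDH4 went from 20.9 ± 4.36 to 1.11 ± 0.434 CPM in A375 and from 1.01 to 4.03 CPM in LOX-IMVI BR. By camera 17 lists differed, but with an estimated correlation their lowest adjusted p was 0.13. Hypoxia genes had lower log2 changes in LOX-IMVI BR (14 members lower and 1 higher, and 25 and 1 adjusted over the list alone; camera adjusted p = 7.74e-14; adjusted p = 0.139 with an estimated correlation). P53 targets (9 higher and 1 lower, and 11 and 2 adjusted over the list alone; camera adjusted p = 0.000106) and ATF4 genes (12 higher and 3 lower, and 18 and 3 adjusted over the list alone; 0.000279) had higher ones. These had adjusted p = 0.152 and adjusted p = 0.339 with an estimated correlation. Upper-quartile factors shifted the median of all genes by −0.167 on the log2 scale, and 67.1% of called genes had higher values without a filter against 44.7%. Leaving out single libraries gave 2675 and 2488 calls without A375 control replicate 1 or 2, 6808 without A375 6-thio-dG replicate 2, 475 and 482 without LOX-IMVI BR control replicate 1 or 2, and 481 and 480 without LOX-IMVI BR 6-thio-dG replicate 1 or 2.

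For BIBR1532 the lines had 239 higher genes and 19 lower genes in common (71.8 and 14.6 if independent), 69 in opposite directions and r = 0.134 across genes. The difference between the lines was called for 1059 genes, 609 higher and 450 lower in LOX-IMVI BR. ANGPTL4, a lipoprotein lipase inhibitor, went from 2.82 ± 0.756 to 138 ± 10 CPM in A375 and from 21.7 to 2.51 CPM in LOX-IMVI BR. C3 went from 12 ± 1.62 to 739 ± 59.7 CPM in A375 and was at 1040 ± 21.4 and 1150 ± 29.9 CPM in LOX-IMVI BR. Mitosis genes (7 higher, and 26 adjusted over the list alone; camera adjusted p = 9.69e-10) and ATF4 genes (16 higher, and 22 higher and 1 lower adjusted over the list alone; 1.17e-08) had higher log2 changes in LOX-IMVI BR. Hypoxia genes (10 lower and 2 higher, and 12 and 2 adjusted over the list alone; 1.17e-06) had lower ones. All 8 lists called by camera had adjusted p = 0.353 with an estimated correlation. GC correction lowered the median difference of mitosis genes from 1.56 to 0.91 and that of DNA repair genes from 1.18 to 0.51. Upper-quartile factors shifted the median of all genes by −0.353 on the log2 scale. The share of called genes that were higher went from 57.5% to 38.1%. A fit of symbol-named genes alone shifted the median of those genes by −0.138, and their share went from 58.4% to 38.5%. The share of all called genes was 69.8% without a filter and 72.8% with voom and group weights. Leaving out A375 control replicate 1 gave 2268 calls, A375 BIBR1532 replicate 1 or 2 149 and 180, LOX-IMVI BR control replicate 1 or 2 152 and 142, and LOX-IMVI BR BIBR1532 replicate 1 or 2 165 and 209.

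The untreated lines differed in 14505 genes, 6132 higher and 8373 lower in LOX-IMVI BR. PEG10, a retrotransposon-derived imprinted gene, was at 2.72 ± 0.251 CPM in A375 and 3220 ± 32.9 CPM in LOX-IMVI BR (log2 fold change 10.21 ± 0.38, adjusted p = 1.6e-09). The bradykinin receptor gene BDKRB1, without counts in A375, was at least 189-fold higher in LOX-IMVI BR. CDKN2A, which encodes the cell cycle inhibitor p16, had no counts in LOX-IMVI BR and was at least 268-fold lower there. Mitosis genes were higher in LOX-IMVI BR in 32 of 45 and lower in 1, by either adjustment (camera adjusted p = 1.05e-07, and adjusted p = 0.43 with an estimated correlation). These genes are low in GC (median 42.5%). For the eighth of genes lowest in GC the control libraries deviated by 0.901 and 0.91 in LOX-IMVI BR and by −0.164 and −0.221 in A375. That difference in GC trend goes with the line, so it cannot be told apart from a difference in mitosis genes here. Interferon-stimulated genes were higher in 27 and lower in 7 of 41, by either adjustment (camera adjusted p = 9.11e-05; adjusted p = 0.313 with an estimated correlation). ATF4 genes were lower in 25 of 44 and higher in 5, and in 29 and 5 adjusted over the list alone (camera adjusted p = 0.000373; adjusted p = 0.44 with an estimated correlation). ERK output was lower in 14 of 24 and higher in 3, by either adjustment (camera adjusted p = 0.00156; adjusted p = 0.355 with an estimated correlation). MLPH, a melanosome transport gene, with 3 counts in LOX-IMVI BR, was 441-fold lower there (95% counting interval 151 to 2140). The number of calls stayed between 10264 and 13673 when single libraries were left out.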

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

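All technical tests of this part were chosen after the results were seen; the differences between the lines were planned. Both compounds were given to both lines, and the effect in LOX-IMVI BR minus that in A375 was tested with edgeR for genes and camera for lists. The difference passed for 1612 genes with 6-thio-dG and 1059 with BIBR1532.

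Of 45 genes named for 6-thio-dG, 24 differed between the lines, 11 of them with log2 changes of opposite sign. Over all genes 1612 of 29114 differed. Most named genes were picked for large changes in 1 line from the same libraries, which by itself raises their share. Some opposite signs rest on changes near 0 in the other line, as for COL1A1 (0.067) and COL3A1 (0.332) in A375. Values are differences in log2 change. Higher values in LOX-IMVI BR were found for KCNH1 (6.20), DYSF (5.72), FAM196B (5.04), CD274 (4.06), GDF15 (3.70), IL18R1 (3.51), EPS8L2 (3.38), S1PR1 (3.17), SLC8A1 (2.28), AOC3 (1.875) and AXL (1.53). Lower values were found for P2RY6 (−12.52), C11orf86 (−10.21), LRRC15 (−7.87), FAM198B (−7.35), COL1A1 (−6.785), COL3A1 (−6.55), ZNF114 (−5.33), STC1 (−5.33), LCE1F (−4.64), DDIT4 (−3.74), THBS2 (−3.62), COL6A3 (−3.18) and HSPA1A (−3.17). C11orf86, LCE1F, KCNH1 and P2RY6 had a group near 0, where the fitted value depends on the prior count.

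For 6-thio-dG 17 lists differed, given as medians of the difference, with members near 0 left out in brackets where that moved the value. Lists with higher values in LOX-IMVI BR were p53 targets 0.94 (0.97), the ATF4 and unfolded protein response 0.92, ERK output 0.89, ribosome biogenesis 0.765 and purine genes 0.57 (0.60). Lists with lower values were fibroblast markers −1.965, hypoxia −1.29, fatty acid synthesis −1.03, extracellular matrix −0.97 (−1.04), interferon-stimulated genes −0.75 (−0.77) and replication −0.63. The others were cholesterol −0.58, autophagy and lysosome −0.55, heat shock −0.54, NRF2 targets −0.48 (−0.56), mitosis −0.47 and secreted inflammatory factors −0.41 (−0.10). With an estimated correlation their adjusted p ran from 0.13 to 0.587. Camera kept the call of 14 of the 17 lists with GC correction.

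Of 44 genes named for BIBR1532, 23 differed, 13 of them with opposite signs. Over all genes 1059 of 29114 differed, and the same selection raises the share of named genes. Some opposite signs again rest on changes near 0, as for HSPA8 (0.304) and NDRG1 (0.252) in A375. Higher values in LOX-IMVI BR were found for KCNH1 (5.77), EFNA1 (4.92), PDE4D (4.32), CDH4 (4.30), BDNF (3.93), GDF15 (3.90), BIRC3 (3.89), ECT2 (3.78), MITF (3.725), PTX3 (3.73), C8orf46 (3.06) and ANGPT4 (2.29). Lower values were found for ANGPTL4 (−8.735), LCE1F (−8.07), CA9 (−6.545), PPFIA4 (−4.42), IL1B (−4.42), PFKFB4 (−3.85), SERPINB2 (−3.79), NDRG1 (−3.41), HSPA8 (−3.25), TUBB3 (−2.80) and AK4 (−1.83). LCE1F, KCNH1 and CA9 had a group near 0. The lists were mitosis 1.56, DNA repair 1.18, ATF4 and unfolded protein response 1.14, ribosome biogenesis 0.92, ERK output 0.75, hypoxia −0.675 (−0.66 without members near 0), extracellular matrix −0.71 (−0.68) and epithelial markers −2.09 (−1.28). With GC correction the medians of mitosis and DNA repair were 0.91 and 0.51, and epithelial markers were not called (camera adjusted p = 0.0756). Each list had adjusted p = 0.353 with an estimated correlation.

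The 2 A375 6-thio-dG libraries lay far apart. So did the 2 A375 control libraries, for which no cause was tested. RNA of the other line in replicate 2 was argued against: 24 genes abundant in LOX-IMVI BR and near 0 in A375 reached a median of 0.394% of their LOX-IMVI BR level there, 0.592% in replicate 1 and 0.379% in A375 control replicate 1. A trend on transcript GC content explained 68.7% of the variance of the log2 ratio of the libraries, so GC-dependent recovery of transcripts is a candidate explanation. Transcript length explained 8.06%, too little to favour it and too much to exclude it. The design gives no biological difference between replicates, so none was tested, and handling or growth of the cells stays open.

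Fibroblast-type genes fell with 6-thio-dG in LOX-IMVI BR. Fibroblasts among the control cells were argued against, because COL1A2, DCN and LUM, abundant in such cells, stood at 2.61, 2.76 and 0.672 CPM beside 1630 CPM of COL1A1, a median of 0.16%. GC-dependent recovery of transcripts was argued against as the whole cause, since 7 of 11 members were called lower with GC correction. A response of the LOX-IMVI BR cells to the compound may explain the fall, as a hypothesis found and tested on the same data. Other technical causes, such as differences in handling between the groups, were not tested.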

How the results depend on the processing

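The corrections for GC content, the fit of symbol-named genes, the split of the controls, the fits of single lines for overlaps, and the voom fit with group weights were chosen after the data were seen. The 2 lines differ in spread, and settings that change how spread is shared moved the counts of called genes. Group weights were 0.202, 0.17 and 1.636 in A375 (control, 6-thio-dG, BIBR1532) and 3.053, 3.088 and 1.887 in LOX-IMVI BR. Where a library was left out, the lone library of its group was assumed to vary like the other groups. Depth limits the folds of genes with 3 or fewer counts in a group, as in the interval of 75 to 1070 for CA9 with BIBR1532 in LOX-IMVI BR. Except where said, the cause of a change was not tested.

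Called genes are given in the order 6-thio-dG and BIBR1532 against control in A375, the same in LOX-IMVI BR, and the compounds against each other in A375 and in LOX-IMVI BR. The reported counts were 5261, 4594, 4939, 1046, 4664 and 5999. The libraries of the line alone gave 1227, 924, 15119, 10802, 1604 and 16112, and with GC correction as well 1981, 1155, 9034, 7340, 1736 and 9300. Voom with group weights gave 290, 2944, 16517, 9397, 1161 and 15811. Symbol-named genes alone, with fewer genes tested, gave 2770, 2169, 2243, 534, 2228 and 2666. GC correction on all libraries tested symbol-named genes and gave 4995, 4646, 4327, 1799, 4536 and 4706, where the reported fit called 2993, 2774, 2451, 546, 2390 and 2931 of them. For the difference between the lines with 6-thio-dG (1612 reported, 1047 of them symbol-named) voom gave 838, GC correction 2989 and no filter 2507. For BIBR1532 (1059 reported, 682 of them symbol-named) voom gave 3755, GC correction 2456, no filter 3002, the DESeq2 test 2047 and symbol-named genes 587. Between the untreated lines (14505 reported, 7919 of them symbol-named) symbol-named genes gave 7896 and GC correction 9143.

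The share of called genes that were higher also depended on the setting. It ran from 21.7% (voom) to 80% (upper-quartile factors) for 6-thio-dG in A375 (54.6% reported) and from 33.3% (voom) to 90.3% (without BIBR1532 replicate 1) for BIBR1532 (53.8%). In LOX-IMVI BR it ran from 44.9% (DESeq2 test) to 73.5% (upper-quartile factors) for 6-thio-dG (57.8%) and from 50% (GC correction in the line alone) to 93.7% (without BIBR1532 replicate 1) for BIBR1532 (80.8%). For the compounds against each other it ran from 19.8% to 60.1% in A375 (45.3%) and from 32.1% to 69.5% in LOX-IMVI BR (48%), with the low values without BIBR1532 replicate 2 and the high ones with upper-quartile factors. The differences between the lines gave 35.8% (without LOX-IMVI BR control replicate 1) to 67.1% (no filter) for 6-thio-dG (44.7%) and 32.2% (without A375 BIBR1532 replicate 2) to 72.8% (voom) for BIBR1532 (57.5%). The untreated lines gave 37.4% (voom) to 47.7% (GC correction), with 42.3% reported.

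Leaving out each library in turn gave 4461 to 10233 and 937 to 5272 called genes for 6-thio-dG and BIBR1532 in A375, and 1550 to 1864 and 209 to 402 in LOX-IMVI BR. The compounds against each other gave 1673 to 8103 in A375 and 2447 to 2770 in LOX-IMVI BR. The differences between the lines gave 475 to 6808 for 6-thio-dG and 142 to 2268 for BIBR1532, and the untreated lines 10264 to 13673.

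Of the lists called by camera (15, 14, 15, 15, 14 and 17 in the order above, 17 and 8 for the differences between the lines, 12 between the untreated lines), an estimated correlation left 1, 0, 8, 1, 5, 6, 0, 0 and 0. GC correction gave 15, 14, 14, 15, 15, 17, 14, 10 and 12. Leaving out single libraries gave 13 to 19, 12 to 14, 15 to 16, 13 to 16, 11 to 15, 17 to 18, 15 to 19, 7 to 16 and 12 to 15 lists, with 16 for the BIBR1532 difference without A375 control replicate 2.

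Genes called the same way with both compounds in A375 (1418 reported) numbered 215 in the libraries of the line alone (22 opposite), and 850 and 691 with the controls split between the compounds. In LOX-IMVI BR (312 reported) they numbered 4886 in the libraries of the line alone (2689 opposite), 702 with GC correction, 194 with the replicate block, and 55 and 50 with the controls split. Each compound then has a single control library, so fewer libraries enter. Across lines they numbered 533 in fits of each line for 6-thio-dG (1274 reported), and 526 with GC correction and 168 with the replicate block for BIBR1532 (258 reported).

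The labels number the replicates but do not say whether a number marks a shared batch, so this stays open. Replicate differences correlated at −0.108, −0.249 and 0.615 between groups in A375 and at −0.009, 0.036 and 0.037 in LOX-IMVI BR. The value of 0.615 was that between 6-thio-dG and BIBR1532. With the replicate number as a block the 9 comparisons called 4516, 4314, 4043, 715, 3672, 5053, 1108, 968 and 13589 genes.

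For 433 named genes with 903 results, no called direction reversed in the settings below. The ranked genes were chosen with all libraries separated, which left little room for a reversal. Fixed genes without a call could turn. TERT in A375 was at 9.46 and 3.89 CPM in the controls and 5.65 and 5.72 CPM with BIBR1532. MDM2 was at 130 and 61.3 against 89.8 and 123 CPM. The direction of both depends on the control library used. Calls were lost in 22 results with DESeq2 factors, 62 with upper-quartile factors, 22 with the DESeq2 test, 21 without a filter, 27 with the 1 CPM filter, 160 in the line alone, 65 with the block and 996 of 4212 with single libraries left out. With the added settings 18 were lost with GC correction, 84 with it in the line alone, 40 with symbol-named genes and 149 with voom. Calls were gained in at most 9. The fits of the line alone covered only 618 of the results, and 619 with GC correction.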

Other observations

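All tests of this part were chosen after the result was seen. In A375 with BIBR1532, genes of the cleavage-stage embryo rose. ZSCAN4, a zinc finger gene of this stage, went from 0.256 ± 0.15 to 14.2 ± 2.56 CPM (log2 fold change 5.98 ± 0.63, adjusted p = 6.02e-05), PRAMEF12 from 0.56 to 45.5 CPM and TRIM43 from 0.139 to 7.9 CPM. CCNA1, the germline cyclin A1, went from 10.4 ± 4.36 to 30.4 ± 1.39 CPM (log2 fold change 1.56 ± 0.38, adjusted p = 0.0159) and RFPL4A from 0.293 to 2.53 ± 0.469 CPM (0.000871). With 6-thio-dG ZSCAN4 stood at 5.26 ± 3.3 CPM, PRAMEF12 at 8.77 CPM and TRIM43 at 0.979 CPM, while TRIM51 fell from 3.8 to 0.779 CPM. In LOX-IMVI BR the highest library held 0.0685 CPM of ZSCAN4.

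A list of 40 such genes was written after 6 of them had been noticed, and 25 were tested. List tests were adjusted over the 4 comparisons with a control. With BIBR1532 in A375 edgeR called 18 higher. Of the 19 not noticed before, 13 were higher, with a median log2 fold change of 3.83 (camera adjusted p = 1.29e-11, and adjusted p = 0.0011 with an estimated correlation). Apart from CCNA1, KDM4E and SLC34A2, these 13 are PRAMEF, TRIM, MBD3L or RFPL genes. PRAMEF and TRIM genes were among the 6 noticed first, and close copies share reads. The list tests with either compound are therefore no independent support. With 6-thio-dG in A375 13 were higher and 1 lower. Of the 19 not noticed before, 8 were higher and 1 lower, with a median of 2.59 (camera adjusted p = 0.000279; adjusted p = 0.0122 with an estimated correlation). In the A375 libraries alone 16 were higher with BIBR1532 and 12 with 6-thio-dG. In LOX-IMVI BR most tested members stood at or below 0.069 CPM in the highest library, so tests of the list decide nothing there.

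Reads shared between near-identical copies were argued against only weakly as the whole cause of the rise with BIBR1532. Of 9 tested members outside the PRAMEF, TRIM, MBD3L and RFPL families 4 were called higher: CCNA1, KDM4E, SLC34A2 and ZSCAN4. ZSCAN4 was itself among the genes noticed first. KDM4E and SLC34A2 were near 0, at 0.0187 and 0.12 CPM in the control and 1.26 and 0.808 CPM with BIBR1532. Among members not noticed first the argument thus rests mainly on CCNA1. GC-dependent recovery of transcripts was argued against too, as 100% of the members called higher stayed so with GC correction. DUX4, which drives such genes in embryos, had 0 counts in the 12 libraries, which cannot decide, since reads of its repeated copies may not have been counted. A response of A375 cells to the compound remains a hypothesis, found and tested on the same data.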
